A study of Mus musculus with 4 samples.

How the data were processed

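The data are 4 CUT&Tag libraries of haematopoietic stem cells isolated from the bone marrow of mice with wild-type Ppp2ca, per the labels: 2 with an antibody to PPP2CA and 2 with IgG. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says that libraries of a group came from separate animals, so any spread between them may be technical.

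The authors deposited 1 peak list per library, in the narrowPeak layout of MACS2. Trimmomatic, BWA, MACS2, deepTools, HOMER and ChIPseeker, and the builds GRCm38 and mm10, are named per the submitters' processing notes, without roles, versions or settings. Each deposited peak has a fold, the ratio of its summit to the local background of its own library. The deposited lists also give the −log10 p and −log10 q of each summit, and a score that the values show to be 10 times the −log10 q for nearly all peaks. Whether an IgG library served as a control in the calling is not given in the sources used here, but the values argue against it. At the 5 best places found in both IgG libraries the PPP2CA summits were 0.208 to 0.227 times the IgG summits, each scaled by the lowest background of its list. Their PPP2CA fold was nevertheless 10.6 to 23.9, which a control scaled in that way would not give. Because each list was called on its own library, these values were used to describe, rank or filter peaks within a list, and the lowest values of the lists were set side by side only in the tests of depth.

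The number of fragments at each summit and its local background were recovered from the deposited fold and −log10 p, taking the fold as (fragments + 1) / (background + 1) and the p as a Poisson tail. This gave whole fragment numbers for 100% of the peaks in each of the 4 lists, with a relative error of at most 2e-05. The lowest background of a list was read as its genome-wide background, which was 0.784 and 0.8 fragments for PPP2CA 1 and 2 and 0.0839 and 0.0833 for IgG 1 and 2. Total reads per library were not used here. Of the IgG 1 and IgG 2 summits, 61.3% and 58.7% held fewer than 5 fragments, so the IgG lists are of low depth. Intervals are exact Clopper-Pearson intervals at 95% and cover counting error only, since fragments amplified by PCR are not independent molecules.

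Overlap meant a shared stretch of at least 1 bp. Peaks of both PPP2CA lists were merged, regions touched by both libraries were called replicated, and those without a peak of either IgG library formed the main PPP2CA set. Random placement moved each peak or region to a random position on its own chromosome, between the first and last annotated or called position, 1000 times in the main comparisons, 200 times for the share of replicated regions with an IgG peak and in the alternatives, and 20 times for reciprocal and summit overlap. Its p counts the placements with at least the observed share and is one-sided. Noise between PPP2CA libraries was the chi-square over degrees of freedom of the fragment counts at summits within 100 bp of each other, after scaling 1 library to the other.

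Genes came from a RefSeq gene table of GRCm38.p6, the build named for the files, which gives gene starts and ends without strand. Windows of 1 kb on each side of both gene boundaries therefore took the place of the windows around transcription start sites that had been planned. Gene entries placed below 3 Mb, where mouse chromosomes other than Y are unassembled, were left out (340 entries of all kinds), and 21779 protein-coding genes were used. A gene counted as marked when a main region overlapped such a window. The 23 gene lists were fixed, and each was compared with all other protein-coding genes by a two-sided Fisher's exact test at a threshold of 0.05, with Benjamini-Hochberg adjustment. The Zfp list was taken by symbol, so not every member need be of the KRAB type, and the histone list holds some replication-independent genes. Where every member of a list had a region, which occurred in some alternatives, 0.5 was added to each count before the odds ratio was taken. Chromosomes were compared by a chi-square test of peak numbers against chromosome length.

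The groups, gene lists, tests, the first set of alternatives and the rule for named genes were chosen before the data were examined. The rule named the PP2A genes with a region, the 12 protein-coding genes with the best regions, the 3 best of each list, the 5 best regions more than 10 kb from a protein-coding gene boundary and the 5 best places found in both IgG libraries. Best meant the worse of the 2 within-library ranks by −log10 q. This gave 88 genes. Of the items the rule named, 1 is not reported here. The other stem cell regulators in the report are given as members of their list, and snRNA genes were named after their values were seen.

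The computations were tested on simulated data. Of 4436 simulated peaks, 100% gave back the exact summit. In 100 rounds on 21779 genes, 93% of lists planted at a share of 75% were called, 100% of those planted at 90% and 1.82% of unplanted lists. In 2 simulated draws from 1 profile the dispersion was 0.86, 0.944 and 0.949 at mean summits of 29, 75 and 230 fragments.

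The alternatives were peaks with −log10 q of 5 or more, equal numbers of peaks, reciprocal overlap of 50%, summits within 200 bp, each library left out, same-numbered IgG libraries, no removal of IgG peaks, windows of 500 bp or 3 kb, summits inside the window, and genes sharing a region counted once. A minimum of 20 summit fragments and regions anywhere in the gene were added after seeing the data, as were the tests of gene classes. The planned search for 23 motifs and the lists matched on base composition need genome sequence, which was not used here. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.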

Results

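Haematopoietic stem cells from mouse bone marrow were profiled by CUT&Tag, an assay in which an antibody tethers a transposase that inserts sequencing adapters into nearby DNA. The study asked where in the genome PPP2CA is found, the catalytic subunit of the serine/threonine phosphatase PP2A. There were 2 libraries with an antibody to PPP2CA and 2 with control immunoglobulin G (IgG). The PPP2CA libraries (replicates 1 and 2) held 16811 and 17686 peaks over 12.5 and 13.6 Mb, and the IgG libraries held 561 and 310 peaks over 0.219 and 0.128 Mb. The median fold of a peak over its local background, the authors' own value, was 5.61 and 5.53 in the PPP2CA libraries and 4.31 and 4.39 in the IgG libraries. The median peak summit held 18 fragments in each PPP2CA library and 4 in each IgG library. The genome-wide background was 9.34 to 9.61 times higher in the PPP2CA libraries, so the 2 kinds of library were not compared at equal depth by these peak numbers. With 2 libraries per group an exact two-sided permutation test cannot give a p below 1 in 3, and none is given.

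The question of the first comparison was whether the places marked with the PPP2CA antibody recurred in its other library. Of the PPP2CA 1 peaks, 75.5% (95% exact interval 74.8 to 76.1) overlapped a PPP2CA 2 peak, and 71.6% (70.9 to 72.3) of the PPP2CA 2 peaks overlapped a PPP2CA 1 peak. Random placement within chromosomes, as a one-sided permutation test, gave 1.16% and 1.11% (p = 0.001, the smallest that 1000 placements can give). At protein-coding genes, 8732 had a peak within 1 kb of a gene boundary in both libraries, 811 in PPP2CA 1 alone and 945 in PPP2CA 2 alone (odds ratio 129). Ppp2ca itself was among the genes marked in both. Recurrence rose with the height of the peak: 28.7% of the PPP2CA 1 peaks with 5 to 9 summit fragments were found again, against 100% of the 904 peaks with 100 or more. The IgG lists shared far fewer places, with 33 of the 561 IgG 1 peaks (5.88%, 4.08 to 8.16) overlapping an IgG 2 peak.

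At shared summits the PPP2CA libraries agree within sampling noise: the dispersion of their fragment counts was 0.783 over 6884 summits and 0.95 over the 1928 summits above 50 fragments, and simulated draws from 1 profile gave 0.86, 0.944 and 0.949 at mean summits of 29, 75 and 230 fragments. Above 200 fragments it was 1.5 (205 summits, one-sided chi-square p = 4.29e-06), and 0.879 (184 summits) without the places called in both IgG libraries. At the shared summits apart from those places the libraries differed by no more than the sampling noise, and they were counted as 1 sample. The 4119 and 5021 merged regions found in PPP2CA 1 or PPP2CA 2 alone were not part of this test. Values are given per library, with no mean or SD, and the spread between animals was not measured.

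**Figure D1:**
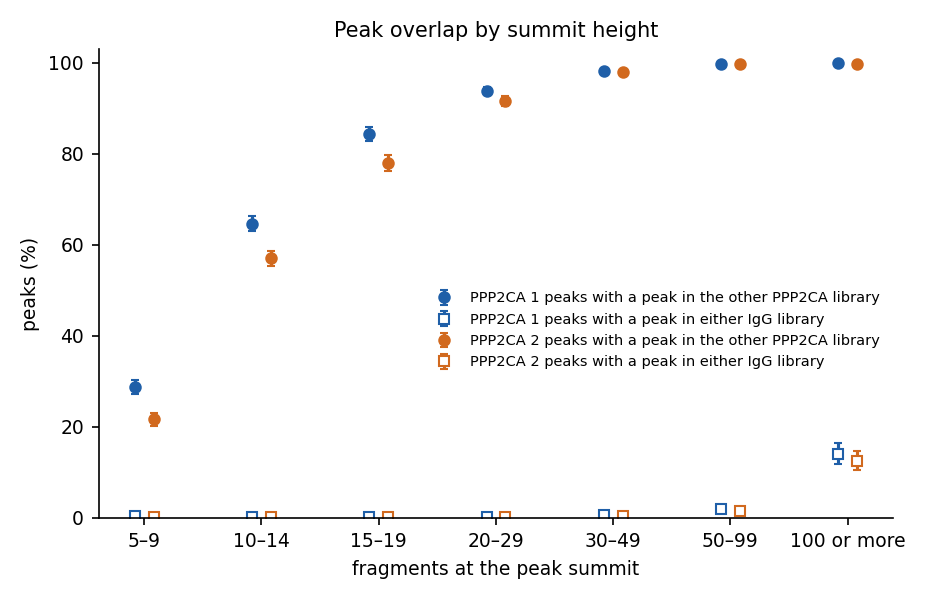
Share of PPP2CA peaks (%) with a peak in the other PPP2CA library (filled circles) and in either IgG library (open squares), by the number of fragments at the peak summit; bars are exact 95% intervals. For PPP2CA 1 the first share goes from 28.7% at 5 to 9 fragments to 100% at 100 or more, and the share with an IgG peak from 0.338% to 13.9%.

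Few of the recurring PPP2CA regions as a whole coincided with a called peak of the control antibody, but most of the best-ranked ones did. The IgG libraries are shallow, with a median summit of 4 fragments. A region without an IgG peak may therefore still carry IgG signal too low to be called. Merging both lists gave 21771 regions, of which 12631 (58.0%) were marked in both PPP2CA libraries. Of these, 193 (1.53%, 1.32 to 1.76) overlapped a peak of either IgG library (0.0491% with random placement, permutation p = 0.005, the smallest that 200 placements can give). Of the 30 best-ranked replicated regions 27 had an IgG peak, as did 13.9% and 12.5% of the PPP2CA 1 and PPP2CA 2 peaks of 100 or more fragments. In the other direction, 28.9% and 29.1% of the IgG 1 peaks and 23.2% and 22.9% of the IgG 2 peaks overlapped a peak of PPP2CA 1 and PPP2CA 2. The best-ranked places found in both IgG libraries, by −log10 q, were on chromosome 2 at 98666554 to 98667307, on chromosome 9 at 3023452 to 3024656, 3000303 to 3000654 and 35305246 to 35305589, and on chromosome 14 at 19417221 to 19417846. None of the 5 lay within 1 kb of a protein-coding gene. The chromosome 2 place held 2701 and 2733 fragments in the IgG libraries and 5349 and 5362 in the PPP2CA libraries, 0.208 times the ratio of the genome backgrounds. At the U2 snRNA gene Rnu2-10, which encodes a spliceosomal RNA and was chosen after its values were seen, IgG held 28 and 17 fragments and PPP2CA 1831 and 2223, 9.51 times that ratio. The share with an IgG peak rested mostly on IgG 1: it was 0.530% without IgG 1 and 1.24% without IgG 2. With only peaks of −log10 q of 5 or more it was 0.454%. With a reciprocal overlap of 50% it was 0.222%, a rule that the narrower IgG peaks (median width 351 and 364 bp) can less easily meet. The 12438 regions without an IgG peak, with a median width of 927 bp and a median fold of 6.30 and 6.27, formed the PPP2CA set used from here on.

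**Figure D2:**
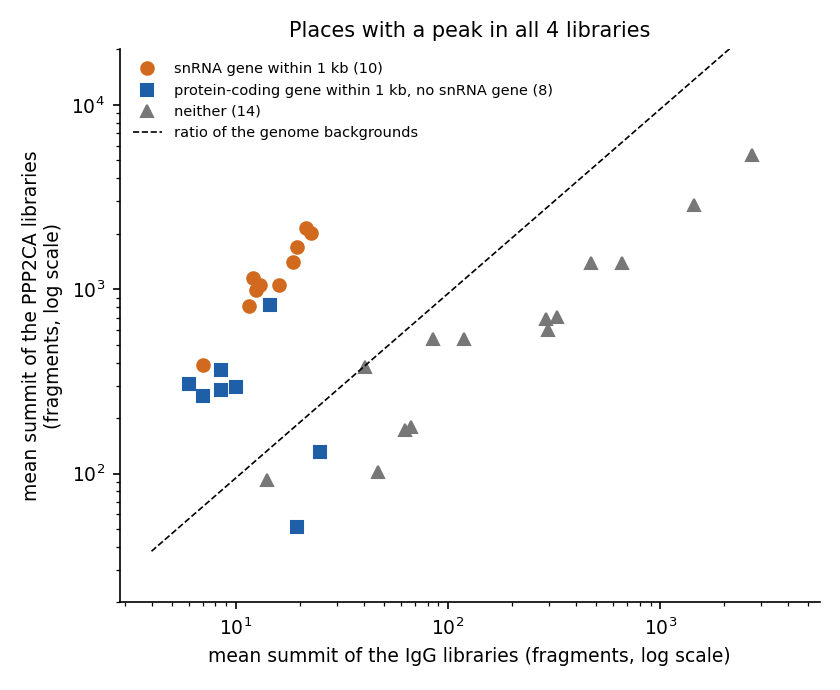
Mean summit height (fragments, log scales) in the PPP2CA libraries against the IgG libraries at 32 places with a peak in all 4 libraries, by the genes within 1 kb; the dashed line is the ratio of the genome backgrounds. The chromosome 2 place at 0.208 times that ratio lies under the line and Rnu2-10, at 9.51 times, above it.

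PPP2CA regions lay mostly at the ends of protein-coding genes. Of the 12438 regions, 7509 (60.4%, 59.5 to 61.2) overlapped the 1 kb on either side of a gene boundary, against 4.73% with random placement (12.8 times, one-sided permutation p = 0.001, the smallest that 1000 placements can give). A further 23.1% lay inside genes and 16.6% outside, against 38.7% and 56.5% at random. Stronger regions were at boundaries more often, from 81.2% of the 1244 best ranked to 35.2% of the 1244 lowest ranked. In all, 8609 of 21779 protein-coding genes (39.5%) had a PPP2CA region at a boundary, 4022 of them at the low-coordinate end only, 3970 at the high-coordinate end only and 617 at both. The gene table used gives no strand, so starts and ends of genes could not be separated. In the single libraries the share was 50.7% and 48.9% for PPP2CA, 18.9% (15.7 to 22.4) for IgG 1 and 11.9% (8.54 to 16.1) for IgG 2. The IgG shares were 5.0 and 3.19 times those of random placement (one-sided permutation p = 0.001 for both, the smallest that 1000 placements can give).

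**Figure D3:**
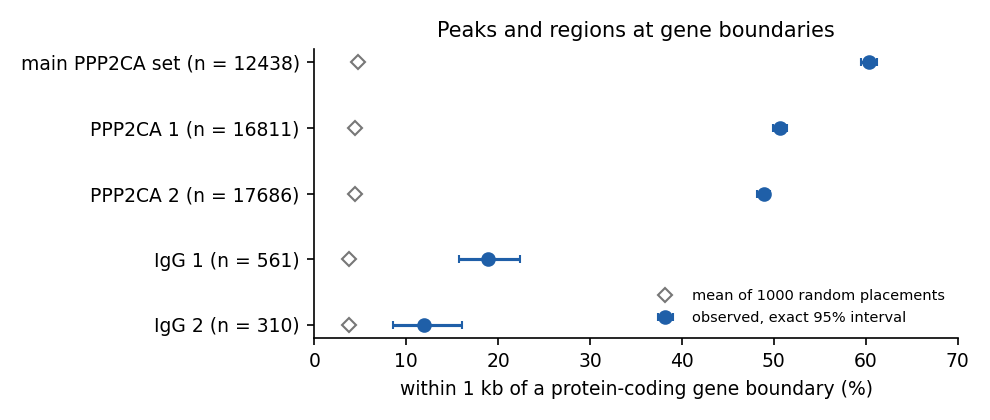
Share (%) of each set of peaks or regions within 1 kb of a protein-coding gene boundary (circles, exact 95% intervals) and the mean of 1000 random placements (open diamonds). The main PPP2CA set is at 60.4%, and the IgG libraries are at 18.9% and 11.9%.

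The gene lists fixed beforehand asked which kinds of gene carried a PPP2CA region at a boundary. A region is a place marked with the PPP2CA antibody, whose specificity was not tested. Of 4 signalling pathways on which PP2A is known to act, 3 were marked more often than other genes and the Wnt and beta-catenin pathway was not called. A PPP2CA region was present at 23 of 24 NF-kappaB pathway genes (Fisher's exact test, odds ratio 35.3, adjusted p = 3.01e-08), 27 of 29 PI3K, AKT, mTOR and FOXO genes (20.7, 1.09e-08) and 31 of 35 MAPK genes (11.9, 1.09e-08). The Wnt and beta-catenin genes had 18 of 35 (Fisher's exact test, odds ratio 1.62, adjusted p = 0.193; Gsk3a, Csnk1a1 and Ctnnb1 the best ranked). In the NF-kappaB list the best ranked by −log10 q were Nfkbia, the inhibitor that holds NF-kappaB in the cytoplasm (416 and 461 fragments in PPP2CA 1 and 2), Relb (286 and 305) and Rnf31 (163 and 164). In the PI3K list they were Akt1s1, Eif4ebp2 and Rheb, and in the MAPK list the MAPK phosphatases Dusp2 (422 and 442 fragments) and Dusp1 (403 and 404), then Map2k2. Each list was tested two-sided against all other protein-coding genes, expressed in these cells or not, with Benjamini-Hochberg adjustment over the 23 lists.

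Genes of the basic machinery of the cell were also marked more often than other genes. They included 72 of 76 ribosomal protein genes (Fisher's exact test, odds ratio 27.8, adjusted p = 1.64e-23; Rpl10, Rplp0 and Rps19 the best ranked), 13 of the 14 Integrator subunits found of 18 listed (19.9, 8.97e-05; Ints6, Ints7, Ints13), 29 of 33 splicing factors (11.1, 3.08e-08; Luc7l2, Srsf5, Srsf2) and 29 of 33 chromatin regulators (11.1, 3.08e-08; Ctcf, Smc3, Ep300). Autophagy and lysosome genes had 22 of 25 (11.2, 1.71e-06; Sqstm1, Atg13, Map1lc3a), proteasome genes 27 of 34 (5.92, 6.87e-06; Psmd5, Psmd1, Psmd3) and oxidative phosphorylation genes 57 of 74 (5.16, 5.25e-10; Ndufa11, Uqcrq, Ndufb1). Histone genes had 52 of 71 (4.21, 3.08e-08), led by H2bc18 and H3c13, which share a region, and H2ac8. Growth and damage control genes were marked too: apoptosis 18 of 23 (5.52, 0.000475; Birc3, Diablo, Birc2), the p53 pathway and DNA damage response 25 of 32 (5.48, 2.32e-05; Btg2, Brca1, H2ax) and the cell cycle 27 of 37 (4.14, 9.55e-05; Cdkn2d, Cdkn1b, Cdk4). Zinc finger genes with Zfp names had a smaller excess, 168 of 367 (Fisher's exact test, odds ratio 1.3, adjusted p = 0.0196; Zfp143, Zfp869, Zfp91), which was lost when summits under 20 fragments were left out (0.954, adjusted p = 0.754).

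The genes of PP2A itself carried PPP2CA regions at 18 of 26 (Fisher's exact test, odds ratio 3.45, adjusted p = 0.00531). Ppp2ca, on chromosome 11 at 52098824 to 52122749, had a region at 52098283 to 52099719, across its low-coordinate boundary, with a fold of 10.3 and 10.2 and 138 and 164 fragments. Ppp2r1a, the alpha scaffold subunit, had a fold of 12.8 and 12.2 (122 and 126 fragments), and the regulatory subunit Ppp2r2d 9.67 and 9.09. The other catalytic gene, Ppp2cb, was lower at 5.21 and 4.47 (21 and 19 fragments). The striatins Strn, Strn3 and Strn4, the subunits Ppp2r1b, Ppp2r2a, Ppp2r3a, Ppp2r3c, Ppp2r5b, Ppp2r5d and Ppp2r5e, the activator Ptpa, the methylesterase Ppme1, the methyltransferase Lcmt1 and the inhibitor Cip2a were also marked. No region within 1 kb of a boundary was found at Tiprl, Set, Ppp2r2b, Ppp2r2c, Ppp2r3d and Igbp1. At the boundaries of Ppp2r5a and Ppp2r5c, only regions with an IgG peak were found. Regions further inside a gene were not counted here. With regions anywhere in the gene the odds ratio of the list was 5.08 (Fisher's exact test, adjusted p = 0.000391). The regions at Lcmt1 (9 and 16 fragments) and Ppp2cb did not pass a minimum of 20 fragments in both libraries, and that at Strn4 lay outside a window of 500 bp.

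None of the lists of blood cell genes was called as marked more often than other genes. Among regulators and markers of haematopoietic stem cells, 16 of 34 had a region (Fisher's exact test, odds ratio 1.36, adjusted p = 0.401). That share was 47.1% (29.8 to 64.9), against 39.5% of other genes, so a moderate excess could have gone uncalled. Egr1, a transcription factor that restrains stem cell proliferation, was the best ranked (1025 and 1128 fragments), then Lyl1 (226 and 233) and Etv6 (47 and 51). Runx1, Tal1, Kit, Meis1, Mecom, Gfi1 and Myb also had a region. Gata2, Erg, Fli1, Hlf, Procr, Cd34 and Slamf1 had none within 1 kb of a boundary, and regions further inside a gene were not counted. With regions anywhere in the gene the odds ratio of the stem cell list was 1.95 (Fisher's exact test, adjusted p = 0.0645), still not called. The erythroid and megakaryocyte markers had 8 of 21 (Fisher's exact test, odds ratio 0.941, adjusted p = 1; Zfpm1, Tfrc, Nfe2) and the myeloid markers 6 of 22 (0.573, 0.308; Cebpa, Spi1, Ngp). Lower than other genes were the lymphoid markers, with Cd3d alone of 25 (Fisher's exact test, odds ratio 0.0636, adjusted p = 0.000158), the stromal and endothelial markers, 3 of 20 (0.270, 0.0442; Sp7, Kdr, Kitl), and the olfactory receptors, with 0 of 1109 (95% upper limit 0.332%, adjusted p = 6.17e-250).

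The stromal call was lost without PPP2CA 2 (Fisher's exact test, odds ratio 0.564, adjusted p = 0.306) and when genes sharing a region counted once (0.319, adjusted p = 0.0713). The Wnt list was higher with only peaks of −log10 q of 5 or more (Fisher's exact test, odds ratio 2.23, adjusted p = 0.0243), without PPP2CA 2 (2.23, adjusted p = 0.0304) and with regions anywhere in the gene (3.49, adjusted p = 0.00119). Without PPP2CA 2 the odds ratio was 31.7 for autophagy, 38.2 for Integrator, 8.45 for the cell cycle, 9.24 for the p53 list, 9.9 for the proteasome, 0.114 for lymphoid and 0.911 for myeloid markers (0.888 without PPP2CA 1), with the same calls. Genes are not independent replicates, and lists were not matched on base composition, expression in these cells or open chromatin. Whether any of these could account for the differences between lists, those of the signalling pathways included, was not tested.

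**Figure D4:**
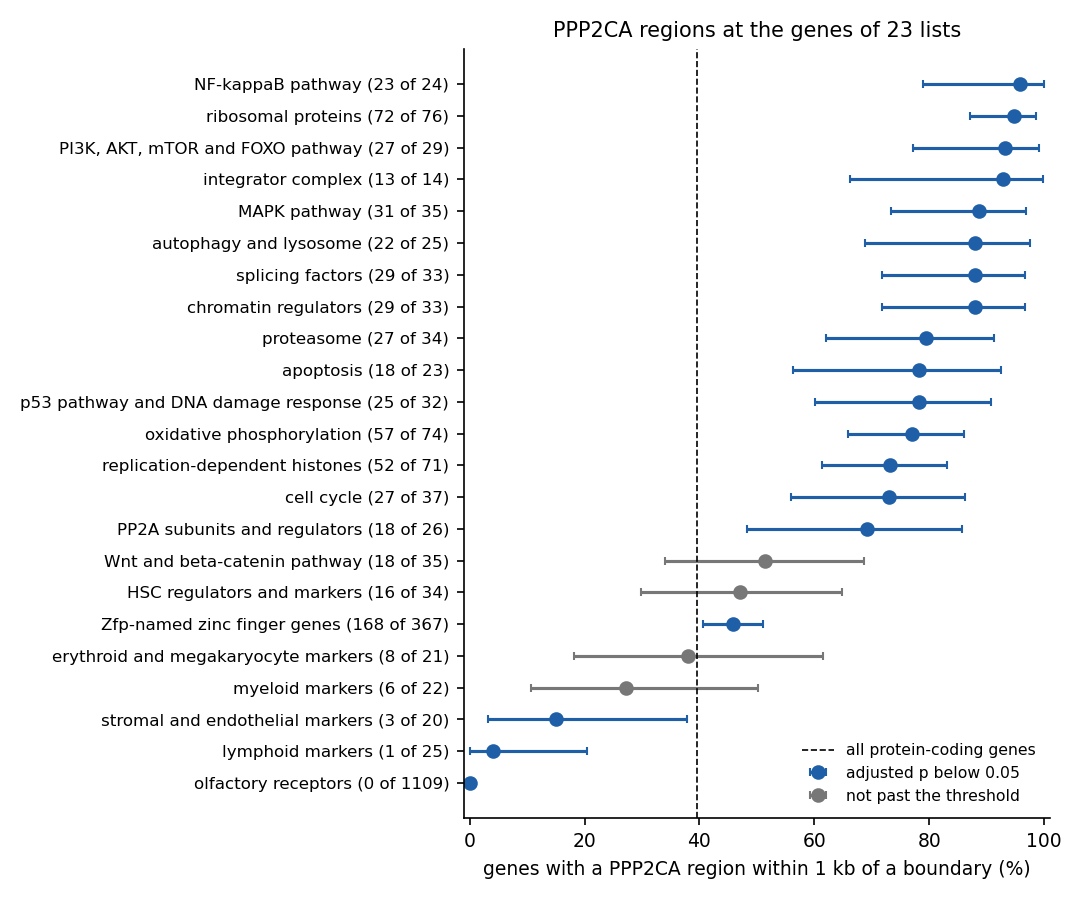
Share (%) of the genes of each of 23 lists with a PPP2CA region within 1 kb of a boundary (exact 95% intervals; counts beside each name), and of all protein-coding genes (dashed line, 39.5%). Of the lists, 16 were higher than other genes, 3 were lower and 4 were neither.

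The best-ranked regions of the PPP2CA set at protein-coding genes, by the worse of the 2 ranks of −log10 q in the 2 libraries, lay at the following genes. The region on chromosome 5 at 115489492 to 115492149 held 899 and 1100 fragments and touched Pxn, the focal adhesion protein paxillin, and Sirt4, with the snRNA genes Gm24265 and Gm24407 also there. Next came Egr1, the translation initiation factor gene Eif1 (fold 11.7 and 12.4), Pnrc1, the endoplasmic reticulum chaperone gene Hspa5 (11.9 and 10.3), the splicing gene Luc7l2, Nfkbia, the splicing gene Sf1, the casein kinase gene Csnk1g2, the MYC antagonist gene Mnt and the initiation factor gene Eif4a1. Their summits held 342 to 1128 fragments. Regions with an IgG peak had been left out of this ranking, among them some at Eapp, Alyref2, Poldip3, Kmt2e and Jun, which were picked out after their values were seen.

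Away from gene boundaries, 2684 regions (21.6%) lay more than 10 kb from every protein-coding gene boundary, some of them inside genes. Among the best ranked were those on chromosome 10 at 130594448 to 130594989 (nearest gene Vmn2r87, 97068 bp away, 432 and 512 fragments), on the X chromosome at 170880930 to 170881283 (nearest gene Asmt, 202875 bp away, 236 and 269) and on chromosome 18 at 12973035 to 12974466, inside Impact (321 and 379). Another was on chromosome 8 at 84197537 to 84198880 near Zswim4 (412 and 452). The first pair were narrow, with a fold of 22.1 to 22.4, against 7.06 to 11.3 for the other 2. A narrow place on chromosome 9 at 35305229 to 35305589, with a fold of 23.9 and 22.4, had a peak in both IgG libraries. The first pair had no peak in either IgG library. A signal equal with both antibodies would be 9.34 to 9.61 times lower at IgG depth. That would still lie well above the lowest called IgG summit of 3 fragments. At these 2 places the values argue against such a signal as the whole cause, and no separate test was made. The median summit held 16.5 fragments more than 10 kb from a boundary and 29.5 fragments at a boundary.

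Chromosomes differed in how many regions they held for their length. Chromosome 11 held 2.03 times the number expected, chromosome 19 1.71 times and chromosome 17 1.53 times, the X chromosome 0.363 times and the Y chromosome 0.0165 times. The single libraries were close, with 2.06 and 2.0 times for chromosome 11 and 0.327 and 0.330 times for the X chromosome. Against an even spread by length, chi-square over 20 degrees of freedom was 2660 and 2626 for the PPP2CA libraries. Chi-square was 88.9 (p = 1.16e-10) for IgG 1, in which chromosome 11 held 2.11 times and the X chromosome 0.311 times the expected number, and 42.7 (p = 0.00223) for IgG 2, in which the ratios were 1.66 and 0.512 and the highest was 1.78, for chromosome 17. Expected numbers followed chromosome length alone and took no account of gene number or of how much of a chromosome reads can map to.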

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

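The minimum of 20 summit fragments, regions anywhere in the gene and the gene class settings were chosen only after the data had been seen. Replicate overlap, 73.5% averaged over both directions, ranged from 58.1% (summits within 200 bp) to 90.9% (gene boundaries) over 5 alternatives, each above its random or independent share. The share of replicated regions with an IgG peak, 1.53%, ranged from 0.222% to 1.52% over 8, and from 0.530% to 1.24% without 1 of the libraries. The gene boundary share, 60.4%, ranged from 48.8% to 70.8% over 9 and stayed above random placement, with 48.8% and 50.6% without PPP2CA 1 and PPP2CA 2. Of 23 lists, 18 to 20 were called over 10 alternatives, with 18 or 19 of the original 19 among them. Odds ratios of nearly full lists rest on few unmarked genes and moved widely, from 13.2 to 63.5 for NF-kappaB (35.3), 5.28 to 71.4 for PI3K (20.7), 6.4 to 81.1 for chromatin regulators (11.1) and 18.5 to 186 for ribosomal proteins (27.8). The range was 8.77 to 60.3 for splicing factors (11.1) and 10.0 to 24.7 for MAPK (11.9). With no IgG peaks removed these 2 lists were at 47.8 and 24.7. With −log10 q of 5 or more, 46 IgG 1 and 26 IgG 2 peaks were left, from 561 and 310, by construction of the stricter threshold. The Zfp odds ratio fell below 1, to 0.954, with 20 fragments as a minimum, and the cause was not tested. Away from protein-coding genes the ratio to random was 0.997 for snoRNA and 0.857 for lncRNA genes. Random placement there still spread all regions over whole chromosomes, which lowers both ratios, so they do not show a lost excess. Of 88 named genes, 83 to 88 kept their region; Lcmt1, Kdr and Kitl lost it in more than 1 setting. Overlap with IgG hardly differed by replicate number: IgG 1 overlapped PPP2CA 1 and 2 in 162 and 163 peaks, and IgG 2 in 72 and 71. These counts cannot tell whether same-numbered libraries shared animals or a preparation, because most peaks of each PPP2CA list recurred in the other. With the replicate block (same-numbered IgG only) the IgG share was 1.52%, the boundary share 60.36% and the lists called 19. The planned motif searches, shuffled sequences and lists matched on base composition were not run. Low peaks recurred less: 28.7% of PPP2CA 1 peaks with 5 to 9 fragments were found again, and whether depth or false peaks account for this was not tested. The IgG lists may miss places that deeper libraries would call.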

Other observations

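The tests of gene classes, of the snRNA pattern and of polymerase classes were chosen only after the strongest regions had been seen, and the list of immediate-early genes was drawn up after Egr1, Jun and Nfkbia had been seen among them.

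PPP2CA regions also lay at genes of small RNAs. Of 403 tRNA genes, 136 (33.7%) lay within 1 kb of a replicated region, 23.1 times the number under random placement. Genes of microRNAs had 110 of 1228 (5.68 times), snRNA genes 61 of 997 (3.99 times), snoRNA genes 77 of 1330 (3.62 times) and lncRNA genes 1988 of 12639 (2.06 times), each with adjusted permutation p = 0.00133. Away from protein-coding genes the excess held for tRNA (19.6 times), snRNA (3.43 times) and microRNA genes (2.74 times), while snoRNA and lncRNA genes were at 0.997 and 0.857 times. The placements still spread all regions over whole chromosomes, and the random share of snoRNA genes was 1.58% here and 1.60% before. Since 60.4% of replicated regions lie at protein-coding gene boundaries, ratios away from these genes are low by design. They cannot show that snoRNA and lncRNA genes lack an excess there. Pseudogenes had 107 of 9854 (0.443 times) and V segments of immunoglobulin and T cell receptor genes 1 of 374 (0.205 times), values that the one-sided test does not address.

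The snRNA genes stood at the top of the ranking by −log10 q, in which order 1 is the best region. Gene classes follow the labels of the gene annotation used here, which lists the U3 genes Rnu3a and Rnu3b1 to Rnu3b4 as snRNA. An snRNA gene lay near 19 of the best 50 replicated regions (38%) and near 0.318% of the other 12581, while tRNA genes lay near 0 of the 50. This is the observation that prompted the tests, so no p is given, and the regions are not independent, since those of Rnu1a1 and Rnu3b1 to Rnu3b4 lie in 1 cluster inside Tex14. The regions at Rnu1a1, Rnu2-10, Rnu5g, Rnu11 and Rnu12, which encode spliceosomal RNAs, at Rnu7, whose RNA processes histone transcripts, and at the U3 genes Rnu3a and Rnu3b1 to Rnu3b4 held 408 to 1831 fragments in PPP2CA 1 and 428 to 2223 in PPP2CA 2. The IgG libraries marked snRNA genes as well, with peaks at 18 of 997 in IgG 1 (36.2 times random, adjusted permutation p = 0.004) and 14 of 997 in IgG 2 (48.1 times, adjusted permutation p = 0.008). Without regions that carry an IgG peak, 41 snRNA genes were left for PPP2CA (2.73 times random).

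For the snRNA pattern, signal that arises whatever the antibody, if the whole cause, would put the PPP2CA over IgG summit ratio, scaled by background, at 1 or below; at the 19 snRNA regions with an IgG peak its median was 8.16, with 18 above 1, against 2.94 at the 114 protein-coding boundaries and 0.620 at the 60 other regions with an IgG peak, and a part from such signal stays open. A neighbouring protein-coding gene boundary as the whole cause meets a value against it. Of the best 50 regions away from every such boundary 36% had an snRNA gene, against 0.464% of the other 4953. Several of these lie in the cluster inside Tex14. Regions that prompted the test are among them, so the share is no separate support for the snRNA pattern itself. Reads shared between the near-identical Rnu3b copies stay open: their summit counts differed by 1.56 times counting noise in PPP2CA 1 (chi-square p = 0.197) and by 7.91 times in PPP2CA 2 (chi-square p = 2.83e-05). Whether small RNA genes of RNA polymerase II differ from those of polymerase III cannot be told, because the polymerase II genes had already been seen at the top of this ranking: the median order was 12 at the 11 of 14 polymerase II genes with a region and 2459 at the 6 of 8 polymerase III genes with one (none at Rnu1b1, Rnu1b2, Rnu1b6, Rny3 and Rnu6), while the median fold was 9.56 and 8.3 (PPP2CA 1 and 2) against 9.23 and 9.6. Binding of the antibody to another protein at these genes was not tested.

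Immediate-early and stress-response genes were a further hypothesis. Of 24 such genes not among those named in the report, 22 had a replicated region, and the best ranked were at Ier2 (516 and 553 fragments), Klf2 (336 and 381, with an IgG peak) and Rhob (229 and 267). Their median order was 694, against 4618.5 for 10000 random lists of genes with a region and 4438 for lists matched on gene length (permutation p = 0.0001 for both, the smallest they can give). In the best 500 were 9 of the 22, against 5.59% of the other genes (Fisher's exact test, p = 1.46e-06). Ccn1 and Egr2 had no region within 1 kb of a boundary, and Fos and Junb also belong to the MAPK list. Whether base composition or expression in these cells could account for the order was not tested.

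For the excess at gene boundaries, transposase insertion into open chromatin whatever the antibody would give IgG peaks a like share, but the upper 95% bound of the IgG share was 22.4%, under the lower bound of 59.5% of the PPP2CA set. That share alone does not decide, since chance peaks could lower it: IgG peaks were at boundaries 5.0 and 3.19 times as often as random placement, and in 55.4% and 41.3% of those overlapping a PPP2CA peak against 3.31% and 2.55% of the rest, a contrast that the split itself sets in part. PPP2CA boundary peaks thinned to the depth of an IgG library, as read from the lowest background of each list, passed that list's lowest −log10 p in 24.7 to 69.8 times as many cases as carried an IgG peak over the 4 pairs of libraries. This count argues against a profile that is the same with both antibodies as the whole cause. GC content, binding of the antibody to other chromatin proteins and a preference for open chromatin that arises only with a bound antibody may each contribute and stay open.

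For the larger peak number of the PPP2CA libraries, a difference in depth predicts a higher lowest fold in the IgG lists. That fold was 2.88 in IgG 2 and 3.31 in IgG 1, against 1.46 and 1.49 in the PPP2CA libraries. The low background of the IgG lists raises it by itself, so this value cannot show that depth lowered the peak number. Thinned to the depth of IgG 1, a mean of 3301 of the 16811 PPP2CA 1 peaks passed, so depth accounts for a part. Depth as the whole cause meets a value against it. PPP2CA peaks thinned to IgG depth still passed in 5.88 to 9.92 times the number of IgG peaks over the 4 pairs. What remains is consistent with enrichment by the PPP2CA antibody, as a hypothesis, and specificity of the antibody was not tested.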
